A study of Mus musculus with 3 samples.

How the data were processed

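The 3 libraries are ribosomal-RNA-depleted total RNA of the chromatin fraction of mouse bone-marrow-derived macrophages, with fragments of 250 to 400 bases per the labels. The labels list 3 biological replicates with separate biosamples and the same donor entry, and do not say whether they came from separate animals or cultures, so that p-values measure only the spread between these samples. Sex and age were not recorded in the labels. The 3 libraries are not copies of each other, since chi-square per gene over pairs of libraries was 68.5 to 115.

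Expected counts per gene and per transcript were computed by the authors and deposited in the layout that RSEM writes, and per the file notes they rest on a transcriptome alignment to mm10 with GENCODE M21. TPM values, by maximum likelihood and as posterior means, were deposited by the authors beside the expected counts and divide them by effective length and scale each library to the same total. The authors also deposited transcript tables with estimated counts and TPM in the layout of kallisto, made from the reads without that alignment. The aligner, the strand setting and the tool versions are not given in the sources used here. Overlapping genes, antisense genes and paralogs could therefore share reads. All 55536 gene rows were matched to the M21 annotation by identifier, which gave symbols, classes and coordinates.

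Rows that name no gene were left out of library sizes and tests. The row of the phiX control genome held 1.94, 0.269 and 0.386% of all counts in replicates 1, 2 and 3, and rows with numeric identifiers held 18, 16 and 8 counts. All 96 ERCC control rows were at 0. Gene expected counts summed to 12602702, 17222239 and 17042691, and estimated counts in the kallisto layout to 19502402, 30678687 and 29638293. A gene was called undetected when its summed expected count was at most 3 in each library. Floors of 3 counts cover counting error only.

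All samples belonged to 1 group, so comparisons were made within libraries. The gene lists, the contrasts between lists, the tests, the rule for named genes and the other settings to be tried were fixed before the data were examined. For each list the median TPM per library was averaged over 3 libraries, and the median of the mean TPM was placed among 10000 random lists of the same size drawn from protein-coding genes with a count in any library. A percentile of at least 97.5 was called high and one of at most 2.5 low, as a description of these libraries. Because these random lists hold no gene without a count, a list of undetected genes falls below them by construction, and lists drawn from all annotated protein-coding genes were added after the data had been seen. Contrasts were differences of mean log2(TPM + 1) between lists, where the pseudocount of 1 shrinks differences of low genes. They were tested by exact two-sided sign flips over 3 libraries, with a smallest p of 0.25. No untreated sample exists in the group, so no background could be subtracted.

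The isoform comparison used limma 3.58.1 in R 4.3.3 on log2 of the summed TPM of retained-intron transcripts over that of protein-coding transcripts, each plus 0.1. Of 9120 genes with both classes, those with a summed mean TPM of at least 5 were tested against 0 with Benjamini-Hochberg adjustment at 0.05, over all tested genes and over each list alone. The slope on log2 starting quantity used edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) on expected counts rounded to whole numbers, as did the coefficient of variation, and DESeq2 1.42.0 was an alternative. TMM factors were 1.01, 1.12 and 0.88. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

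Named genes were, from each list, the 3 highest and the lowest detected members, all undetected members, and all members of lists of at most 12 genes. The 15 protein-coding and 10 other genes with the highest mean TPM and the 10 most variable genes with a mean TPM of at least 10 could also be named. So could the 10 genes with the largest isoform ratio in each direction, every inducible gene past that threshold, and the 5 genes with the largest slope in each direction. Genes outside this rule are marked where they appear, and the most variable protein-coding genes, the Y-linked and imprinted genes and those of other tissues were added after the data had been seen.

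The methods were tested on simulated data. In the slope test with 200 of 12859 genes changed, a log2 slope of 1 was recovered for 93.0% at a coefficient of variation of 0.14 and for 6.0% at 0.33, a slope of 2 for 100.0 and 96.5%, and a slope of 3 for 100.0% at either. In the isoform test on 4311 genes, ratios of 1, 2 and 4 on the log2 scale were recovered for 0.0, 51.5 and 88.0% of 200 changed genes, and for 56.4, 87.7 and 97.1% of 2000 changed genes. False calls numbered 0, 8 and 16 beside 0, 103 and 176 recovered genes with 200 changed. With 2000 changed they numbered 36, 48 and 67 beside 1127, 1753 and 1942. Of 200 simulated lists of 20 genes, 5 with no change were called high and 5 low, and lists raised 4, 16 and 64 times were called high in 120, 194 and 200 cases.

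Alternatives were kallisto sums, posterior mean TPM, expected counts as CPM, another pseudocount, filters on low values, other normalisations and tests, and leaving out each replicate. TPM was also rescaled after leaving out mitochondrial and small RNA genes, which raised every other gene by 1.51, 0.89 and 1.08 log2 in replicates 1, 2 and 3. Rescaling and class shares without the genes of the chromosome 17 rRNA locus were added after the data had been seen. The results of 1 of the fixed gene lists are not reported here.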

Results

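Chromatin-bound RNA was measured in mouse macrophages grown from the bone marrow of C57BL/6J animals. The cells had been given Lipid A, the part of bacterial lipopolysaccharide that is sensed by Toll-like receptor 4 (TLR4), at 100 ng/ml for 12 h. They had then spent 12 h without it and had been given the same dose again for 60 min. RNA of the chromatin fraction holds transcripts that are still being made or have not yet left the nucleus. The 3 libraries, replicates 1, 2 and 3, formed 1 group with no untreated arm and no arm with a single dose. The values are therefore levels in twice-dosed cells and not responses to Lipid A. Gene counts summed to 12602702, 17222239 and 17042691 in replicates 1, 2 and 3, which were made from 1000, 250 and 500 ng of RNA. A gene with no count could have been present at up to 0.238, 0.174 and 0.176 CPM (counts scaled to the library total), the level of 3 counts. Of 55536 annotated genes, 11052 had a TPM (length-scaled transcript abundance) of at least 1 in all 3 libraries, among them 8568 protein-coding genes and 961 long noncoding RNA genes.

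The protein-coding gene with the most chromatin RNA was Lilrb4a (ENSMUSG00000112148.1, mm10 chromosome 10, 51490956 to 51496611, + strand), an inhibitory receptor of myeloid cells, at 2962 ± 557 TPM (SD, n = 3). Isoforms of Lilrb4a annotated as protein coding held 0.37, 0 and 1.84 TPM in replicates 1, 2 and 3. Those annotated as retaining an intron held nearly all the rest. The level of a gene sums all its annotated isoforms, so levels and their order depend in part on which isoforms are annotated. The neighbour and paralog of Lilrb4a, Lilr4b, reached 2320 ± 372 TPM, and the division of reads between them is uncertain. The MHC class I gene H2-K1, which also has near copies, stood at 2207 ± 155 TPM. Tnfaip2 followed with 1756 ± 501 TPM and Malt1, a protease of NF-kB signalling, with 1724 ± 583 TPM. Acod1, which makes itaconate in activated macrophages, stood at 1522 ± 144 TPM, the transcription factor gene Zeb2 at 1513 ± 90.8 TPM and Sirpa, the macrophage receptor for CD47, at 1240 ± 52.1 TPM. The splicing factor gene Rbm39 had 1159 ± 234 TPM (1761 TPM with kallisto) and the ferritin gene Fth1 had 1130 ± 328 TPM.

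A planned comparison set genes that restrain or carry NF-kB signalling against the components of the TLR4 pathway. All 19 NF-kB feedback regulators had at least 10 TPM in every library, with a median of 135 ± 12.2 TPM. Tnip3, an A20-binding inhibitor (ENSMUSG00000044162.12, chromosome 6, 65525313 to 65634040, + strand), led with 705 ± 142 TPM. Tnfaip3, which encodes the ubiquitin-editing enzyme A20, had 585 ± 99 TPM and Traf1 had 370 ± 58.7 TPM, while the deubiquitinase gene Cyld was lowest at 14 ± 6.53 TPM (SD, n = 3). The 24 TLR4 pathway genes had a median of 36.1 ± 1.49 TPM. Within that list Ikbke, a kinase upstream of interferon regulatory factors, reached 1447 ± 123 TPM, its relative Tbk1 257 ± 14.4 TPM and the kinase gene Irak2 253 ± 12.4 TPM. The adaptor gene Tirap was lowest at 1.46 ± 0.381 TPM. The feedback regulators exceeded the pathway genes by 1.79 ± 0.16 in mean log2(TPM + 1), in 3 of 3 libraries. The exact two-sided sign-flip test gave p = 0.25, the smallest value that 3 libraries allow, so no such contrast could pass a threshold of 0.05. Summing kallisto transcript values put Irak2 at 426 TPM and Tirap at 5.37 TPM.

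Interferon-stimulated genes formed the highest inducible list. All 26 were at or above 10 TPM in every library and 18 at or above 100 TPM, with a median of 207 ± 38.8 TPM. The antiviral GTPase gene Mx1 (ENSMUSG00000000386.15, chromosome 16, 97447035 to 97462907, − strand) had 1100 ± 312 TPM, Rsad2, which encodes viperin, 711 ± 195 TPM and the guanylate-binding protein gene Gbp5 700 ± 148 TPM (SD, n = 3). The exonuclease gene Isg20 was lowest at 27.7 ± 12.9 TPM. Of 9 type I interferon genes, Ifnb1 alone was detected, at 7.36 ± 4.34 TPM with 60, 21 and 85 counts in replicates 1, 2 and 3. Ifna1, Ifna2, Ifna4, Ifna5, Ifna6, Ifna9, Ifna11 and Ifna12 had no more than 3 counts in any library. The chemokine list of 18 genes had a median of 67.7 ± 35.5 TPM, with 48.4, 46 and 109 TPM in replicates 1, 2 and 3. Ccl5 stood at 1074 ± 104 TPM, the neutrophil chemoattractant gene Cxcl2 at 414 ± 51.9 TPM and Cxcl10 at 386 ± 162 TPM, whereas Cxcl9 had 0.187 ± 0.121 TPM and Ccl17 was not detected. Chemokine genes lay below interferon-stimulated genes, with a difference of −2.75 ± 0.29 log2 in 3 of 3 libraries (exact sign-flip p = 0.25). With only genes of at least 1 TPM on average the difference was −1.44. With kallisto sums Rsad2 stood at 1098 TPM and Cxcl9 at 1.08 TPM.

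Cytokine genes were compared with antimicrobial and effector genes. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, − strand) had 605 ± 40.7 TPM, Il1b 308 ± 87.7 TPM and Il1a 199 ± 45.8 TPM, while Csf3, which encodes the granulocyte colony-stimulating factor, had 0.143 ± 0.107 TPM (SD, n = 3) from 1, 4 and 2 counts. The median of the 16 cytokine genes was 15 ± 9.52 TPM, with 14.6, 5.7 and 24.7 TPM in replicates 1, 2 and 3. It was lowest in replicate 2, the library with the stromal RNA described below. Il6 and Il12b, both named after their values had been seen, had 12.5, 5.07 and 16.7 TPM and 14.3, 3.16 and 46.1 TPM in replicates 1, 2 and 3. Among the 21 effector genes Acod1 was followed by Clec4e, a receptor for mycobacterial glycolipid, at 880 ± 109 TPM and the mitochondrial superoxide dismutase gene Sod2 at 610 ± 176 TPM. Mmp9 had 0, 8 and 0 counts, all in replicate 2, the library with the stromal RNA, and Slpi, Camp and Hp were not detected. The median of the effector list was 21.8 ± 6.11 TPM. Cytokine genes differed from effector genes by −0.67 ± 0.39 log2 in 3 of 3 libraries (exact sign-flip p = 0.25), and by −1.12 in CPM, without division by length. The cytokine list stood at percentile 99.6 of the random lists with all libraries and at 95.7 without replicate 3. With kallisto sums Il1b stood at 484 TPM and Il12b at 34.9 TPM on average. Of the 28 gene lists, 15 were high and 7 low among random lists of protein-coding genes with a count. Among random lists of all annotated protein-coding genes, added after the data had been seen, 18 were high and 0 low.

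Immediate early genes, which are switched on within minutes of a stimulus, were low beside the feedback regulators 60 min after the second dose. The median of 22 genes was 14.6 ± 1.2 TPM. The transcription factor gene Klf6 reached 265 ± 28.2 TPM, and the phosphatase genes Dusp2 and Dusp1 reached 131 ± 19.5 and 130 ± 20.8 TPM (SD, n = 3). Fosb had 3, 13 and 28 counts in replicates 1, 2 and 3 and Fosl1 was not detected, and Fos, named after its value had been seen, had 10.6 ± 1.45 TPM. Immediate early genes differed from the NF-kB feedback regulators by −3.08 ± 0.05 log2 in 3 of 3 libraries (exact sign-flip p = 0.25). Anti-inflammatory mediators had a median of 21.7 ± 2.91 TPM over 16 genes. Cd274, the gene of the ligand PD-L1, had 240 ± 49.2 TPM, Zfp36, whose product destabilises cytokine mRNAs, 106 ± 28.1 TPM and the oxysterol receptor gene Nr1h3 85.5 ± 27.8 TPM. Pdcd1lg2 was lowest at 0.307 ± 0.116 TPM and Arg1 was not detected.

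**Figure D1:**
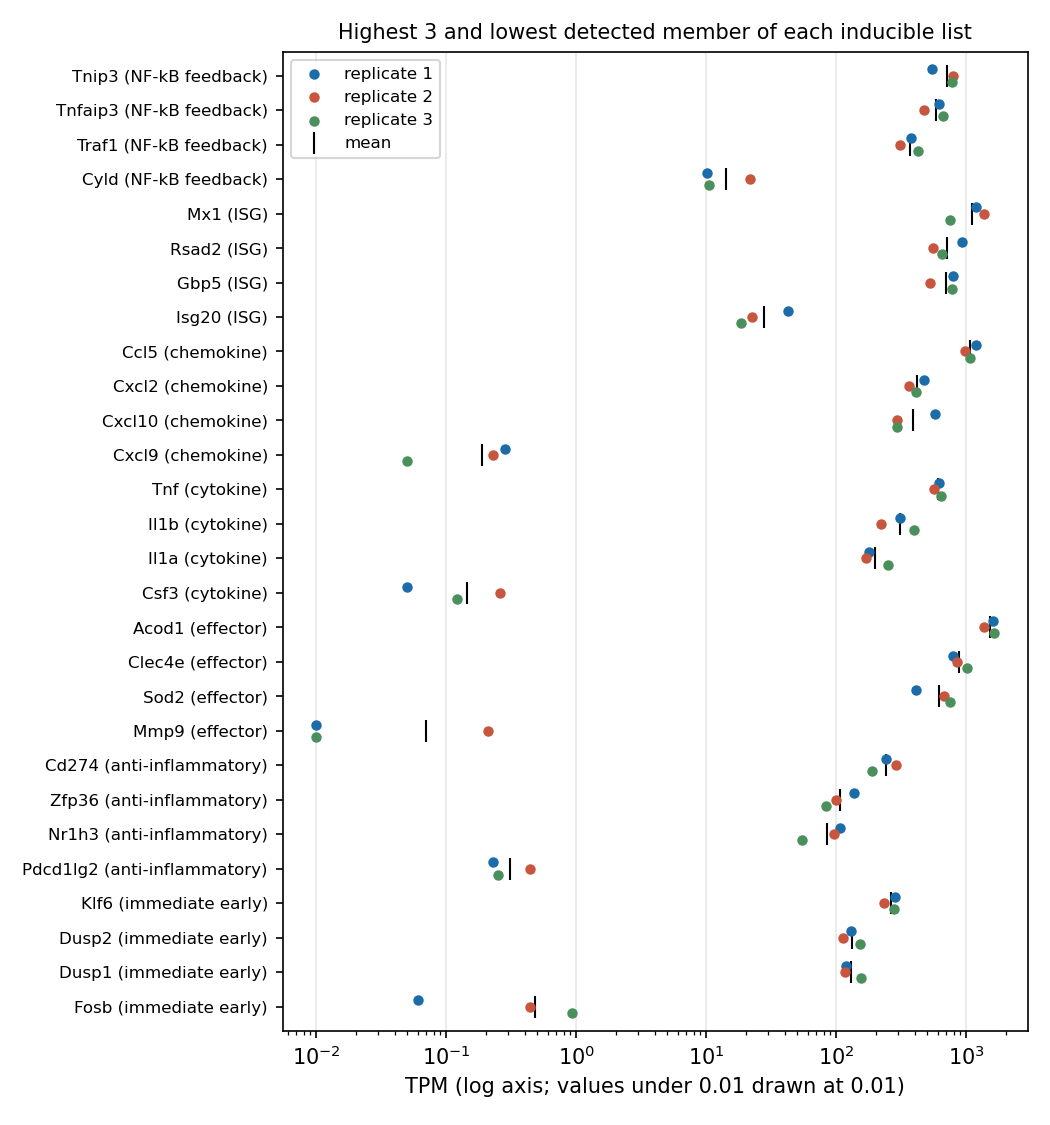
TPM (log axis) of the highest 3 and the lowest detected member of each inducible list in replicates 1, 2 and 3, with the mean as a black bar; values under 0.01 are drawn at 0.01. Acod1 and Mx1 had means of 1522 and 1100 TPM, and Mmp9 had a mean of 0.07 TPM, all from replicate 2.

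Markers of macrophages were compared with markers of other cells that bone marrow cultures can hold. The 24 macrophage identity genes had a median of 53.1 ± 8.73 TPM. Adgre1, which encodes the surface marker F4/80, had 441 ± 140 TPM, the lysosomal protease gene Ctsb 343 ± 74 TPM and the scavenger receptor gene Msr1 314 ± 17.2 TPM, while Lyz1 had 0.177 ± 0.119 TPM (SD, n = 3) from 5, 1 and 2 counts. Joined into 1 list of 87 genes, the markers of other cells lay 4.73 ± 0.17 log2 below the macrophage genes in 3 of 3 libraries (exact sign-flip p = 0.25). With a pseudocount of 0.1 in place of 1 the difference was 7.02. All 12 neutrophil markers were undetected. Of 14 T and NK cell markers, 12 were undetected, while Thy1 had 0, 153 and 0 counts in replicates 1, 2 and 3. Among 10 B cell markers Cd22 had 86, 82 and 13 counts and Ebf1 0, 65 and 0. Among 10 markers of mast cells and basophils Hdc had 53, 30 and 30 counts, Kit 19, 13 and 27, and Gata2 1, 11 and 0. Of 10 erythroid markers found in the files, Tfrc had 402, 1176 and 349 counts, Alas2 37, 17 and 20, and Epor 0, 6 and 0, while the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were not detected. Thy1, Ebf1, Gata2 and Epor passed 3 counts in replicate 2 alone, the library with the stromal RNA. The median of 10 dendritic cell markers was 0.293 ± 0.0701 TPM, and Bst2, which macrophages also transcribe, had 64.6 ± 19.5 TPM. The median of 10 endothelial and megakaryocyte markers was 0.0683 ± 0.0275 TPM, with Vwf highest at 25 ± 5.2 TPM. Kallisto sums gave some of these markers more RNA, with Cd3d at 14.4 TPM and Thy1 at 13.9 TPM among T and NK cell markers, Cxcr2 at 4.31 TPM among neutrophil markers, Ebf1 at 2.19 TPM, Hdc at 2.5 TPM, Alas2 at 10.3 TPM and Bst2 at 115 TPM.

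Fibroblast and stromal markers stood apart in replicate 2. Their summed counts were 3, 43483 and 106 in replicates 1, 2 and 3, and 11 of 11 markers were highest in replicate 2. Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042, + strand), which encodes a chain of type I collagen, had 0, 16804 and 36 counts. Col1a2 had 0, 11612 and 25 counts and the chemokine gene Cxcl12 had 0, 539 and 0 counts. The median of the list was 0, 21.4 and 0.05 TPM, and the list lay at percentile 87.2 of the random lists of genes with a count with all libraries and at 0.3 without replicate 2. Macrophage identity genes were also higher in replicate 2 than in the mean of the others, in 22 of 23 genes above 1 TPM in a library, with a median log2 difference of 0.45 beside 0.57 for all protein-coding genes.

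**Figure D2:**
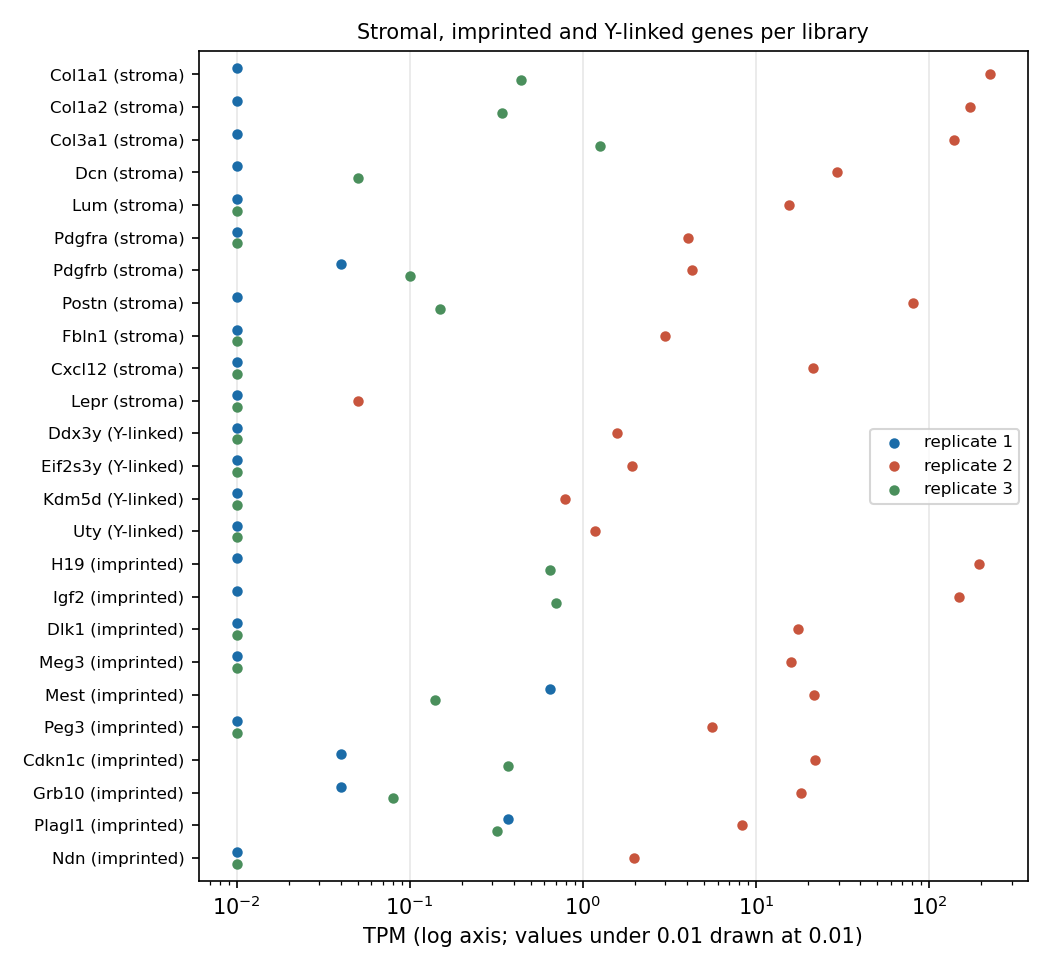
TPM (log axis) of stromal, Y-linked and imprinted genes in replicates 1, 2 and 3, with values under 0.01 drawn at 0.01. Col1a1 had 0, 224 and 0.44 TPM and H19 had 0, 195 and 0.65 TPM in replicates 1, 2 and 3; the Y-linked and imprinted genes were added after the data had been seen.

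Nuclear long noncoding RNAs were compared with mRNAs made in mitochondria. Malat1 and Neat1, long noncoding RNAs of nuclear bodies, had 23215 ± 7211 and 1897 ± 373 TPM, and Xist, which coats the inactive X chromosome, had 1027 ± 212 TPM (SD, n = 3). Tsix, which overlaps Xist on the other strand, had 0.143 ± 0.14 TPM and cannot be separated from it without strand information. The median of the 13 nuclear long noncoding RNAs was 9.58 ± 5.6 TPM, at percentile 88.0 of the random lists of genes with a count and 97.7 of those of all genes. A list of 12 small RNAs, fixed as nuclear, also held the mainly cytoplasmic 7SL RNAs Rn7s1 and Rn7s2 and Y RNAs Rny1 and Rny3, and its median was 1863 ± 742 TPM. In it Rmrp, the RNA of the RNase MRP complex, had 81155 ± 31685 TPM over its 2 annotated copies. Rn7sk, which holds the elongation factor P-TEFb inactive, had 16566 ± 3364 TPM, and Rny1 and Rny3 were not detected. With kallisto sums Rmrp had 33566 TPM, Rn7sk 8814 TPM, Rny1 4.94 TPM and Rny3 15.6 TPM. Mitochondrial mRNAs had medians of 24.9, 96 and 36.2 TPM, highest in replicate 2, the library with the stromal RNA. The mt-Atp8 mRNA had 132, 676 and 255 TPM, but 116, 154 and 74 counts in replicates 1, 2 and 3. Its TPM thus overstates the difference in counts. The mt-Co1 mRNA had 209, 401 and 205 TPM. Kallisto sums gave means of 110 TPM for mt-Atp8 and 199 TPM for mt-Co1. As shares of the counts, mitochondrial mRNAs took 0.0556, 0.0812 and 0.0413% in replicates 1, 2 and 3. The tables differed on mt-Co2, mt-Atp6 and mt-Nd3, which had no more than 3 counts in the RSEM layout, and on mt-Co3, which had 0, 2 and 239 counts there, highest in replicate 3. Kallisto gave mt-Co2 1, 786 and 581 counts in replicates 1, 2 and 3, mt-Atp6 666, 1426 and 569, mt-Nd3 0, 193 and 42, and mt-Co3 899, 2217 and 611. For mt-Nd4l, named after its values had been seen, the counts were 39, 88 and 0 in the RSEM layout and 73, 232 and 113 from kallisto. The 13 mitochondrial mRNAs summed to 7009, 13982 and 7034 counts, and to 10708, 21136 and 9831 in the kallisto tables. Nuclear long noncoding RNAs exceeded mitochondrial mRNAs by 0.83 ± 0.44 log2 in 3 of 3 libraries (exact sign-flip p = 0.25). The direction did not hold across quantifications, being −0.15 with kallisto sums and −0.49 with posterior mean TPM.

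By transcript class, protein-coding genes took 63.7 ± 5.33% of the counts and long noncoding RNA genes 31.2 ± 6.27% (SD, n = 3). Small RNA took 2.13 ± 0.774%, pseudogenes 0.843 ± 0.23%, mitochondrial mRNA 0.0594 ± 0.0202%, mitochondrial rRNA 0.00589 ± 0.00438% and the remaining classes 2.03 ± 0.187%. As shares of TPM, small RNA took 54.4 ± 9.48% and protein-coding genes 30.6 ± 4.07%. Part of the long noncoding share lay in Gm26917, with 1296986, 3338002 and 3117501 counts in replicates 1, 2 and 3, and Gm42418, with 91489, 463191 and 353075 counts. Gm42418 overlaps the annotated rRNA gene CT010467.1 (chromosome 17, 39846353 to 39848827, − strand), which was counted under small RNA, and Gm26917 ends just before it. Without these 3 genes the long noncoding share was 16.5 ± 2.38%. Among the other genes at the top of the TPM scale were the snoRNA genes Gm22988 at 84534 ± 40835 TPM and Snord15b at 36482 ± 13130 TPM, with effective lengths of 2.5 to 12.9 bases. Kallisto sums gave them 16964 and 7596 TPM.

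**Figure D3:**
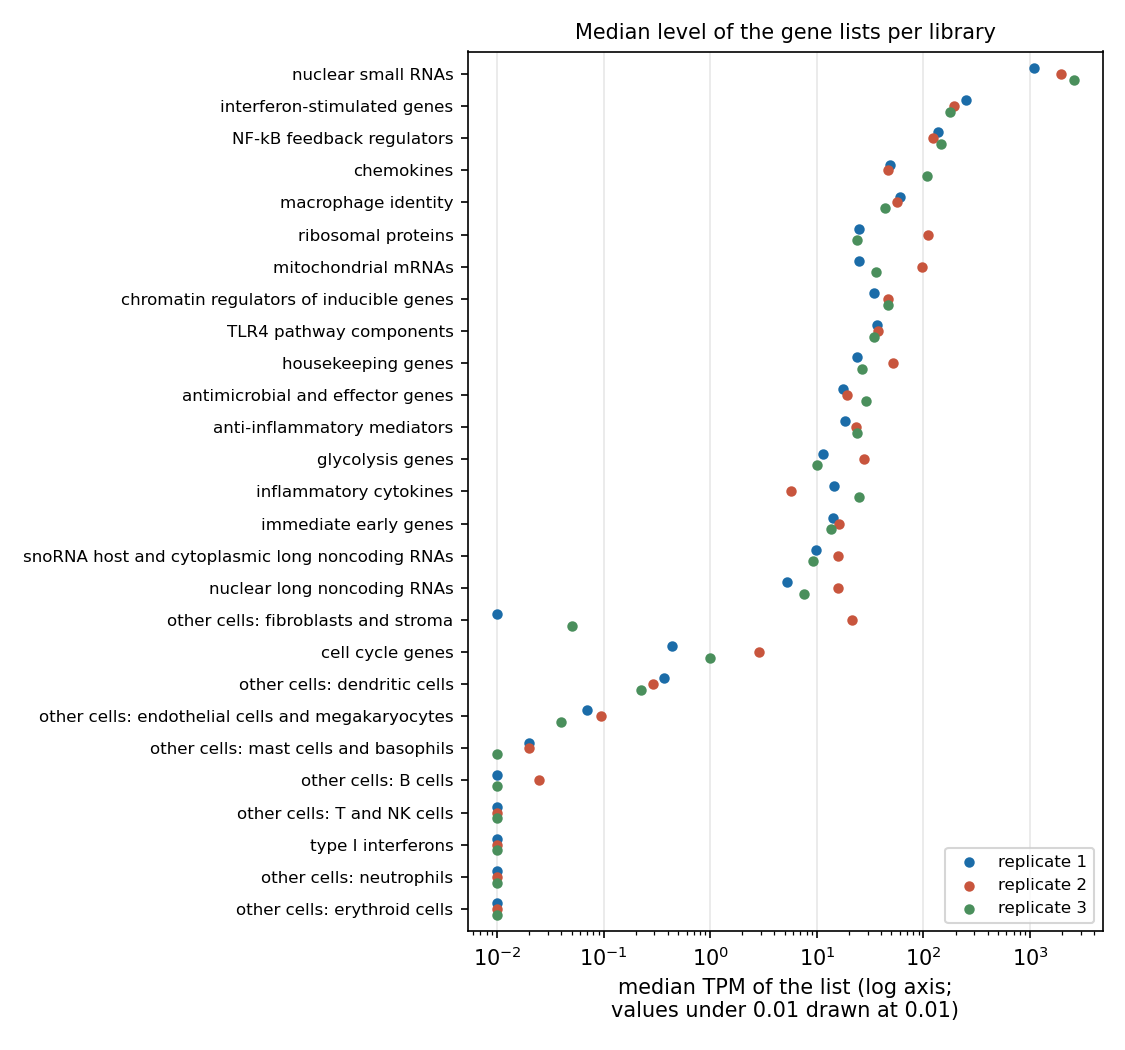
Median TPM (log axis) of the gene lists reported here in replicates 1, 2 and 3, with values under 0.01 drawn at 0.01. The interferon-stimulated genes lay at 177 to 251 TPM, and the stromal markers at 0, 21.4 and 0.05 TPM.

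Within genes, isoforms annotated as retaining an intron were compared with protein-coding isoforms, because chromatin RNA can be incompletely spliced. Of 4311 genes tested with limma, 1049 had more RNA in the retained-intron class, 1104 had more in the protein-coding class and 2158 did not pass the threshold. The balance depended on the values used, with 1810 genes in the retained-intron class from kallisto and 3404 in the protein-coding class from expected counts. The ratio depends on the number and length of the models in each class, so that 0 on the log2 scale marks equal TPM and not equal splicing, and it leaves out isoforms of other classes. Among NF-kB feedback regulators, 3 of 14 leaned to the retained-intron class and 5 to the protein-coding class, also 3 and 5 when adjusted over the list alone. Nfkb1, which encodes the p105 precursor, had a log2 ratio of 3.07 (SE 0.30, adjusted p = 0.0041) and Tnip3 of 2.55 (SE 0.21, adjusted p = 0.0034), while the inhibitor gene Nfkbia had −3.09 (SE 0.23, adjusted p = 0.003) and Nfkb2 −3.24 (SE 0.24, adjusted p = 0.003). Among interferon-stimulated genes 4 of 17 leaned to the retained-intron class and 3 to the other, again 4 and 3 when adjusted over the list alone. Mx2 had 6.14 (SE 0.21, adjusted p = 0.0016) and Irf7 2.27 (SE 0.19, adjusted p = 0.0034), against −4.42 (SE 0.19, adjusted p = 0.0017) for Oas2. Mx2, annotated as a polymorphic pseudogene, had 411, 271 and 228 TPM in replicates 1, 2 and 3, of which the retained-intron class held 109, 33 and 40.5 TPM, so that most of its RNA lay outside the ratio. In the effector list Clec4e had 2.76 (SE 0.22, adjusted p = 0.0033), and 3 of 5 genes leaned to the retained-intron class and 1 to the other, with 3 and 1 adjusted over the list alone. Each of these ratios had 1 sign in 3 of 3 libraries. With expected counts the ratio of Sod2 went from 1.62 to −3.28 and that of Oasl1 from 1.11 to −0.66, and Slc7a11 at 0.90 and Tnfaip3 at 0.48 no longer passed. With kallisto values Tnfaip3 at 0.12 (adjusted p = 0.56) and Zbp1 at 0.16 (adjusted p = 0.45) no longer passed. Kallisto values gave Nfkbia a ratio of −0.92, Nfkb2 of −2.44, Nfkb1 of 2.41, Tnip3 of 1.65 and Mx2 of 6.86.

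The chemokine list had 2 of 7 genes past the threshold toward the retained-intron class and 0 toward the other, with 2 and 0 adjusted over the list alone. Cxcl10 had a log2 ratio of 1.29 (SE 0.27, adjusted p = 0.019), and the other call, Ccl6, went from 0.97 to −0.86 with expected counts. Anti-inflammatory mediators had 0 and 3 of 6, with 0 and 3 adjusted over the list alone, led by the interleukin-1 receptor antagonist gene Il1rn at −4.76 (SE 0.31, adjusted p = 0.0029). Cytokines had 0 and 1 of 2, with 0 and 1 adjusted over the list alone, where Csf1 had −2.08 (SE 0.22, adjusted p = 0.0049). Immediate early genes had 1 and 1 of 3, with 1 and 1 adjusted over the list alone. There Dusp1 had 10.22, 3.32 and 3.25 in replicates 1, 2 and 3. Kallisto values gave −5.94 for Il1rn, −2.86 for Csf1 and 3.99 for Dusp1, and Klf6 at −0.07 (adjusted p = 0.74) no longer passed, nor did Dusp1 with expected counts. TLR4 pathway genes had 7 and 5 of 18, with 7 and 5 adjusted over the list alone. Macrophage identity genes had 1 and 4 of 7, with 1 and 5 adjusted over the list alone. Across all tested genes the highest ratios were those of Lilrb4a at 12.66 (SE 0.79) and Slc27a1 at 7.55 (SE 0.56), with the isomerase gene Hyi between them. The lowest were those of the phosphodiesterase gene Pde4b at −9.79 (SE 0.19), Gtf2ird2 at −8.82 (SE 0.28) and Ccdc88b at −8.42 (SE 1.14). The smaller class was at 0 TPM in all libraries for Pde4b, Gtf2ird2 and Hyi and in some for the others, so that the added 0.1 sets the size and order of these ratios. Kallisto values gave 10.22 for Lilrb4a, 6.81 for Hyi and 4.48 for Slc27a1, and −6.70 for Pde4b, −7.47 for Gtf2ird2 and −3.52 for Ccdc88b. Of 2112 called genes also tested with kallisto values, 1981 had the same sign and 1738 also passed there, but Relb, Trem2 and Zc3h12a changed sign. Without replicate 3 the calls numbered 351 and 473, and without replicate 1 the retained-intron calls numbered 676.

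**Figure D4:**
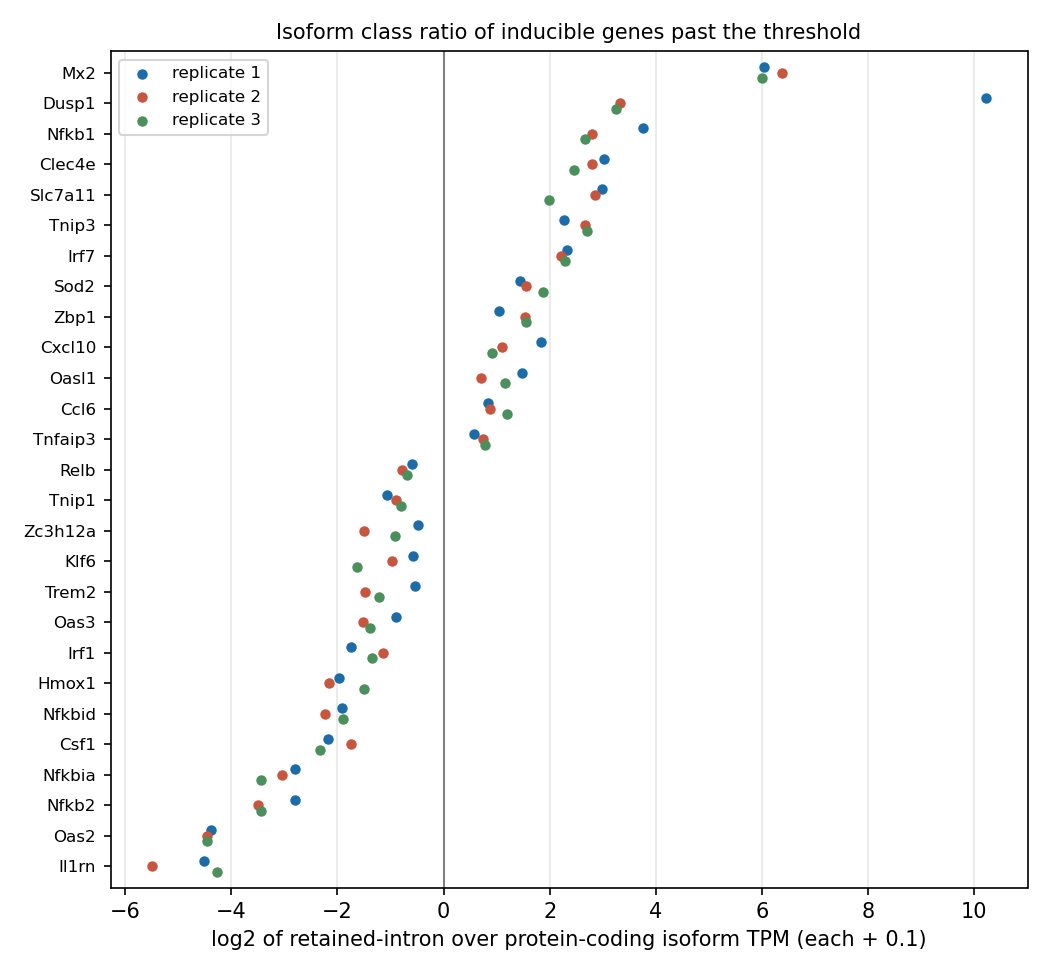
Log2 ratio of retained-intron to protein-coding isoform TPM, with 0.1 added to each, for genes of the inducible lists past the limma threshold, in replicates 1, 2 and 3. Mx2, most of whose RNA lay in other isoform classes, was highest at 6.14 on average and Il1rn lowest at −4.76.

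The amount of RNA that entered each library differed, and genes were tested for a slope on it with edgeR. Of 12859 genes, 62 were higher with more starting RNA and 60 lower. Without the filter on low counts these were 220 and 1128, so that the balance between them depended on the filter. Of the 62, 42 were small RNA genes, led by Gm24305 with a log2 slope of 2.95 per doubling of the quantity (adjusted p = 0.00032) and Gm22614 with 2.92 (adjusted p = 0.00032), the latter listed with the same values as Gm25890. Replicate 1 was highest for 46 of the 62. Effective lengths also differed between libraries, with 25.9, 5.9 and 7.1 bases in replicates 1, 2 and 3 for Gm22513, another of these genes. The quantity cannot be told apart from that difference. Of the 60, 59 were protein coding and all 60 were highest in replicate 2, which had both the least starting RNA and the stromal RNA. They were led by the cadherin gene Cdh11 with −3.86 (adjusted p = 0.0011), the procollagen enhancer gene Pcolce with −2.99 (adjusted p = 0.0037) and the microfibril gene Mfap4 with −2.82 (adjusted p = 0.0054). Igfbp4 had −2.69 (adjusted p = 0.0053) and the gelatinase gene Mmp2 −2.62 (adjusted p = 0.016). The slope left 1 residual degree of freedom and the quantity cannot be separated from other differences between the 3 libraries. Limma-trend on log2(TPM + 1) called 0 genes in either direction, with 1795 at an unadjusted p under 0.05 against 1245 in edgeR and 698 in DESeq2, which called 64 and 32.

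Ribosomal protein mRNAs, which every cell holds, had medians of 24.8, 110 and 23.6 TPM in replicates 1, 2 and 3. All 25 were higher in replicate 2, the library with the stromal RNA, by a median log2 difference of 2.04 against 0.57 for all protein-coding genes. Rpl10 had 67.5, 248 and 107 TPM and Rps3 10.2, 46.5 and 11.9 TPM, and kallisto sums put the mean of Rpl10 at 76.6 TPM. Across protein-coding genes, Pearson's r of log2(TPM + 1) was 0.973 between replicates 1 and 3, 0.932 between 1 and 2, and 0.930 between 2 and 3, taken across genes, which are not independent replicates. The biological coefficient of variation over 12859 genes was 0.33 in edgeR, and 0.27 without replicate 2. The most variable genes with at least 10 TPM on average were Gm26447, Snord22 and Snora26, snoRNA genes with effective lengths down to 0.0 bases. Col1a1 was the most variable protein-coding gene, with an SD of 4.37 in log2(TPM + 1).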

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

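No test was run on the values of this part, and none was chosen after a result was seen. Signal above 3 counts stood in rows that no comparison used. The row of phiX, a control genome that is added to sequencing runs, held 249336 counts in replicate 1, 46477 in replicate 2 and 65984 in replicate 3. Rows with numeric identifiers, which name no gene, held 18, 16 and 8 counts in replicates 1, 2 and 3.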

How the results depend on the processing

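Rescaling and class shares without the genes of the chromosome 17 rRNA locus, and random lists from all annotated protein-coding genes, were chosen only after the data had been seen, and the other alternatives were planned. Of the values of the 6 contrasts under the alternatives, 58 kept their direction and 2 reversed. The chemokine contrast ranged from −3.78 to −1.44, the NF-kB contrast from 1.72 to 1.90, the cytokine contrast from −1.12 to −0.48, the immediate early contrast from −3.42 to −2.71 and the macrophage contrast from 3.74 to 7.02. Nuclear long noncoding RNAs minus mitochondrial mRNAs reversed to −0.15 with kallisto and −0.49 with posterior mean TPM, and leaving out replicates gave 0.66 to 1.08. The cause was not tested. All these contrasts have n = 3 and could not pass a threshold in any setting. For list percentiles, 235 values stayed on their side of the limits, 7 passed a limit they had not passed and 10 no longer passed. With random lists from all annotated protein-coding genes, 6142 of which had no count, 0 lists were low in place of 7, because genes without a count then stood in the random lists too. Immediate early genes stood at percentile 97.4 with kallisto, cytokines at 95.7 without replicate 3 and mitochondrial mRNAs at 97.3 with expected counts as CPM. Dendritic cell markers stood at 1.4 with posterior mean TPM and 1.3 without replicate 1, stromal markers at 0.3 without replicate 2 and nuclear long noncoding RNAs at 98.5 with expected counts as CPM. Of 201 single-gene levels 76 moved by more than 1 SD with kallisto, 78 with posterior mean TPM and 139 with rescaling, the last because rescaling multiplies all values. By more than 1.5 times, a limit set after the data had been seen, 16 moved without replicate 1, 44 without replicate 2 and 5 without replicate 3, and the mean of Col1a1 went from 74.8 to 0.22 TPM without replicate 2.

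A TPM minimum of 5 left 6243 detected genes, by construction, and kallisto gave 17318. As shares of TPM, protein-coding genes took 30.6%, long noncoding RNA 12.8%, small RNA 54.4% and mitochondrial mRNA 0.104%, since division by length raises short genes. Without the rRNA-locus genes the protein-coding share was 78.1% and the long noncoding share 16.5%.

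Genes with more RNA in the retained-intron class numbered 1810 with kallisto, 681 with a minimum TPM of 20, 283 against a 2-fold ratio and 351 to 901 with a replicate left out. Those with more in the protein-coding class numbered 552 with a minimum TPM of 20, 3404 with expected counts, 388 against a 2-fold ratio and 473 to 849 with a replicate left out. Fewer genes or samples entered with the higher minimum and with a replicate left out, and for the others the cause was not tested. Ratios of single genes kept direction and call in 346 cases, lost the call in 56 and reversed in 8. The reversed ratios were, with expected counts, Ccl6 at −0.86, Oasl1 at −0.66, Sod2 at −3.28, Relb at 0.12 and Trem2 at 1.31, and with kallisto Relb at 0.21, Trem2 at 2.68 and Zc3h12a at 0.56. The cause was not tested.

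Genes higher with more starting RNA numbered 220 without a filter on low counts and 0 with limma-trend. Genes lower with more starting RNA numbered 32 with DESeq2, 33 with RLE in edgeR, 1128 without a filter and 0 with limma-trend. Genes at an unadjusted p under 0.05 numbered 1245 in edgeR, 698 in DESeq2 and 1795 in limma-trend. The cause was not tested, and no replicate could be left out of a slope over 3 libraries. The coefficient of variation was 0.38 for genes with a mean TPM of at least 10, 0.35 with kallisto and 0.27 to 0.35 with a replicate left out, lowest without replicate 2. Depth limits single genes near the floor of 0.174 to 0.238 CPM.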

Other observations

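All tests of explanations in this part were chosen only after the results had been seen, while the levels of the gene lists were planned. Genes of chromatin regulators that act at inducible genes were high in the chromatin RNA, with a median of 42.5 ± 6.94 TPM over 15 genes (SD, n = 3). Brd2, a reader of acetylated histones, had 258 ± 23.8 TPM, Tet2, which oxidises 5-methylcytosine, 184 ± 7.13 TPM and the corepressor gene Ncor1 131 ± 30.8 TPM, while the Polycomb methyltransferase gene Ezh2 was lowest at 7.02 ± 2.96 TPM (12.8 TPM with kallisto). The list stood at percentile 100.0 of 10000 random lists. So did the lists of housekeeping, ribosomal protein and TLR4 pathway genes, so a high level was not particular to chromatin regulators. In the isoform comparison 2 of 12 of these genes leaned to the retained-intron class and 5 to the protein-coding class, also 2 and 5 when adjusted over the list alone.

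Glycolysis genes had medians of 11.3, 27.6 and 10.1 TPM in replicates 1, 2 and 3, and 14 of 15 were higher in replicate 2, which also held the stromal RNA, than in the mean of the others, though not all of these were highest there. Pkm had 43.3, 112 and 41.2 TPM, whereas Pfkp had 51.9, 41.8 and 69.1 TPM and Pfkfb3, which makes an activator of glycolysis, 29.8, 48.8 and 53.9 TPM. Slc2a1, the glucose transporter GLUT1, was lowest at 2.25 ± 0.635 TPM, and kallisto sums put it at 5.35 TPM and Pfkfb3 at 66.6 TPM. Housekeeping genes had medians of 24, 52 and 26.3 TPM, with 14 of 14 higher in replicate 2 than in the mean of the others, and Eef1a1 had 262, 737 and 273 TPM against 649, 664 and 425 TPM for Actb. The median log2 difference was 0.75 for housekeeping genes and 1.26 for glycolysis genes, beside 0.57 for all protein-coding genes. In the isoform comparison, 3 and 3 of 12 glycolysis genes, 1 and 1 of 10 housekeeping genes and 2 and 2 of 20 ribosomal protein genes leaned to the retained-intron and protein-coding class. When adjusted over the list alone these were 3 and 3, 0 and 0, and 1 and 0. Cell cycle genes had a median of 1.44 ± 1.27 TPM, at percentile 25.2 of random lists of genes with a count and 74.9 of those of all genes, with 0.44, 2.87 and 1 TPM in replicates 1, 2 and 3, and the highest were Mki67 at 114 ± 23 TPM and Pcna at 19.6 ± 1.24 TPM. Among 9 snoRNA host and cytoplasmic long noncoding RNAs, at percentile 93.2 and 98.3 of these with a median of 11.6 ± 3.73 TPM, Gas5 had 131 ± 34.8 TPM and Snhg1 32.9 ± 5.11 TPM.

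The fibroblast and stromal RNA of replicate 2 came to 2525 CPM over 11 markers, beside 0.238 in replicate 1 and 6.22 in replicate 3. Macrophages that transcribed these genes in all cultures would have shown them in the other libraries. These values are the pattern itself, however, so they do not test cytoplasmic RNA of the macrophages as the source. Of the protein-coding genes above 5 TPM in replicate 2 and under 0.2 TPM in the others, 39 could be compared. Their median isoform ratio was −5.92 log2, at percentile 0.00 of 10000 random lists matched on level. The lists were not matched on the number and length of models in each class, on which the ratio depends. These genes were also not measured in the chromatin of stromal cells. The ratio therefore does not decide whether stromal cells went through the chromatin isolation like the macrophages. RNA of other cells or of another sample also stays open. Stromal counts of 3 in replicate 1 and 106 in replicate 3, beside 43483 in replicate 2, argue against carry-over from either of these libraries. Carry-over from a library outside these 3 cannot be told apart from RNA of another sample. The Y-linked genes did not decide, because 4 of them had 0, 217 and 0 counts in the RSEM layout but 541, 1324 and 1137 in the kallisto layout. Of the latter, Kdm5d alone held 464, 689 and 680. Imprinted growth genes such as H19 and Igf2 had 21, 14405 and 56 counts, whereas markers of epithelium had 0, 9 and 0, of muscle 3, 9 and 4, of neurons 0, 17 and 0, and of liver 2, 1 and 2. Replicate 2 also had the least starting RNA, and beyond RNA of other cells no biological explanation was tested.

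The share of long noncoding RNA differed between replicates by 11.5 percentage points, from 24 to 35.5% of the counts. Without the long noncoding genes Gm26917 and Gm42418 and the rRNA gene CT010467.1 beside them the range was 4.6 points. The mean share also fell, from 31.2 ± 6.27% to 16.5 ± 2.38% (SD, n = 3), so that a narrower range follows in part from the smaller share. Reads of these neighbouring genes may account for part of the spread. Whether they came from rRNA left after depletion was not tested, and no biological explanation was tested.

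Ribosomal protein mRNAs were higher in replicate 2 by a median of 2.04 log2, with quartiles of 1.70 and 2.68. Macrophage identity genes were higher by 0.45, with quartiles of 0.14 and 0.92, and mitochondrial mRNAs by 1.59, with 9 of 10 genes higher. All protein-coding genes were higher by a median of 0.57, so the identity genes rose no more than genes as a whole. Small RNA took 64.6, 45.9 and 52.7% of TPM in replicates 1, 2 and 3, which raises other genes in replicate 2. Part of each difference therefore follows from scaling to a common total. As shares of the counts, mitochondrial mRNAs took 0.0556, 0.0812 and 0.0413%. The identity genes go against cytoplasmic RNA of the macrophages as the whole cause only if it raised all of their mRNAs alike. The mitochondrial mRNAs go with cytoplasmic RNA of some source, so this explanation stays open. The isoform ratio of 20 ribosomal protein genes lay −2.98 log2 from that of the other replicates, beside −0.16 for all genes. Broadly expressed genes moved the same way, with −1.78 for 10 housekeeping genes and −0.93 for 12 glycolysis genes. The difference was −0.20 for 7 macrophage identity genes and −0.51 for 6 anti-inflammatory mediators. For 61 macrophage identity and inducible genes together it was −0.04. The source of the stromal RNA may thus also have brought the ribosomal protein mRNAs. Spliced RNA of any other source would move the isoform ratio in the same direction, so the ratio does not single out a source. No biological explanation was tested.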
